A study of Mus musculus with 9 samples.

How the data were processed

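RNA was measured in 9 libraries of mouse bone marrow macrophages, 3 each of Control, JHU083 and WGFT17 cells. Libraries were stranded by the dUTP method, made from poly(A) RNA and sequenced as read pairs of 150 bases. The submitters' processing notes name cutadapt 1.9, HISAT2 2.2.1, StringTie 2.1.6, DESeq2 and edgeR, without their roles or settings, and the genome build mm9. One table was used, with 28998 genes. Per the labels and its header, it holds an expected count (here called estimated count) and an FPKM value for each gene and library. The deposited FPKM values, made by the authors, are fragments scaled to transcript length and depth, with 2 decimals. The deposited expected counts are whole numbers not scaled to depth, so they needed no rounding. Their pattern, with an excess of genes at 4 and 8, is that of values derived from read coverage, in which 1 read pair gives about 4 counts. Totals were 60438656, 65293390 and 65950611 in Control, 60121889, 64726148 and 56624220 in JHU083, and 68057542, 69112134 and 66436251 in WGFT17, and between 21556 and 22424 genes per library were above 0. The coordinates in the table equal those of GRCm38 (GENCODE M21) for 26125 of 28926 matched gene identifiers (90.3%), not those of mm9, so positions are given in GRCm38. Columns were assigned to groups by the labels' sample titles and the file header, and all per-sample columns were matched.

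Genes with a mean FPKM of at least 1 over the 9 libraries were tested (11798). The main test was edgeR 4.0.16 quasi-likelihood on the estimated counts, with TMM factors and all 9 libraries in 1 fit, run under R 4.3.3. P-values were adjusted by Benjamini-Hochberg within each comparison, and a gene was called changed at an adjusted p under 0.05. The common dispersion was 0.01486, a biological coefficient of variation of 0.122. A limma fit of log2 FPKM had been planned before the data were examined; since the table also holds counts, the count model was used and the FPKM fit (limma 3.58.1, pseudocount 1, 0.1 or 0.01) became an alternative. Means and SDs in the text are those of the deposited FPKM. SEs belong to the log2 changes of the count fit.

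Gene lists were written from general knowledge before the files were opened: 47 lists with 1176 entries, of which 1158 are in the table. The 44 lists with at least 5 tested genes were tested with camera from limma at a preset correlation of 0.01, on log2 CPM with a prior count of 2; p-values were adjusted over the lists of a comparison. The other 3 lists had 3, 3 and 2 tested genes. Camera was repeated with the correlation estimated from the data, and fry was run beside it, which asks whether a list's genes move 1 way on balance and does not compare them with other genes. Counts adjusted over the list alone apply Benjamini-Hochberg to the members of that list.

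Genes were named by a fixed rule. It takes the 8 largest rises and 8 largest falls of each comparison among changed genes with at least 5 FPKM in the higher group and no overlap between the groups, leaving out provisional symbols. It adds up to 4 members with the smallest adjusted p of each called list and 2 of each other list, and a fixed set of genes of glutamine use, stress and macrophage activation. The fixed lists of heart, retina and liver genes, and the same rule with these genes left out, were added after the data were seen. Genes named outside the rule, chosen after their values were seen, are Pdgfra, H2-Aa and Cd74, the 4 examples of opposite change, the values per library of Cebpb, and Neat1, Malat1 and Xist in WGFT17. Nos2, Il1b and Il6 are in the fixed set but under the FPKM filter. The text gives a part of the genes that the rule names. Results of 2 of them are withheld and not reported here, though the list tests include these 2.

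Alternatives planned in advance covered the pseudocount, filters of no minimum and of 5 FPKM, median-ratio, upper-quartile and quantile scaling, fits of 2 groups only, the replicate number as a block, other variance models, library weights, a minimum fold of 2 and leaving out each library in turn. Alternatives added after the data were seen were DESeq2 1.42.0, counts divided by 4, filterByExpr, library totals alone, terms for the libraries that carry retinal or heart transcripts, removal of each library's trends on transcript GC content and length (loess, span 0.3), and leaving out genes of other tissues. GC content and length, those of each gene's longest annotated transcript, were found for 11791 tested genes. For the ribosomal and respiratory lists, 10000 lists of genes matched on length, GC content and level were drawn from 50 neighbours of each gene. For the shared calls, 20 simulations drew groups without an effect against 1 set of Control libraries. The 6 libraries of each comparison were also divided in all 10 ways into 3 and 3.

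The method was tested on simulated data with 11798 genes, of which 200 changed, at the depth and dispersion of these libraries. Per comparison, it found 96%, 92% and 92% of genes changed 2-fold, 68%, 66% and 68% at 1.5-fold and 20%, 22% and 26% at 1.25-fold. False calls were 5.33%, 4.14% and 2.05% of the calls. Small changes were thus often missed in these simulations. Far more genes were called in the data, which makes the adjusted threshold less strict there. The shares found are therefore not the sensitivity of the comparisons reported here. Intervals and SEs cover the spread between these 9 libraries only.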

Results

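The samples were macrophages grown from bone marrow monocytes of C57 mice. GM-CSF, a growth factor that drives this differentiation, was given for 7 days, and the drug groups were then treated for 36 h. There were 3 groups of 3 libraries, named Control, JHU083 and WGFT17. JHU083 is known as a prodrug of DON, a glutamine antagonist that blocks enzymes using glutamine as a substrate. WGFT17 is a code name, and its structure and target were not used here. The labels give no doses and no treatment time for Control, and they do not say what the Control cells received. Whether Control cells were kept for the same 36 h is thus unknown. A difference in culture time could not be told from a drug effect in either comparison with Control. Poly(A) RNA was sequenced as stranded read pairs of 150 bases. The deposited estimated counts summed to between 56624220 and 69112134 per library. About 4 of these counts stand for 1 read pair, so the totals correspond to about 14200000 to 17300000 pairs. Of 28998 genes in the table, 11798 had a mean FPKM of at least 1 and were tested. The labels do not say whether replicates came from separate cultures or animals, so the p-values measure only the spread between these libraries.

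In a principal component analysis of the tested genes, the first component held 70.3% of the variance. The WGFT17 libraries scored 58.3 to 59.2 on it, the Control libraries -40.3 to -38.9 and the JHU083 libraries -28.9 to -8.20. The next component held 11.2%. On it JHU083 replicates 1 and 2 scored -24.1 and -36.5, whereas JHU083 replicate 3 scored 2.40 and the Control libraries 13.4 to 15.0.

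Transcripts that belong to tissues other than bone marrow were present and differed between libraries. Summed over 20 heart muscle genes, CPM (counts scaled to the library total) were 375 to 430 in Control, 294, 4.59 and 458 in JHU083 replicates 1 to 3, and 1.9 to 2.39 in WGFT17. Summed over 14 photoreceptor genes of the retina, they were 38.1 to 46.2 in Control, 5.99, 5.50 and 42.9 in JHU083, and 3.79 to 4.44 in WGFT17. For 25 liver genes, the sums were 1640 to 1840, then 627, 292 and 956, then 378 to 824. These 3 lists were written after the data were seen. The retinal transcripts thus set the 3 Control libraries and JHU083 replicate 3 apart from the other 5 libraries. Only JHU083 has libraries on both sides, with replicate 3 alone on the carrying side and so without a spread of its own. A term for this split beside the 3 groups compares JHU083 replicate 3 with JHU083 replicates 1 and 2. By it 1536 genes differed, 521 higher and 1015 lower in replicate 3. For 752 of them all 4 carrying libraries lay on that side of all 5 others. That separation is partly built in, since the genes were picked by JHU083 replicate 3 lying apart. Also, 73.2% of all tested genes showed no overlap between WGFT17 and Control. The 752 thus do not show a common cause in the 4 libraries. Of the 76 genes at least 2-fold higher in replicate 3, 5 belong to the heart, retina or liver lists. The gene of the transcription factor Cebpb (chromosome 2, 167688915 to 167690418 in GRCm38 coordinates) had FPKM of 3.69, 3.63 and 4.04 in Control, 38.8, 36.3 and 1.47 in JHU083, and 65.9, 67.2 and 66.3 in WGFT17.

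**Figure D1:**
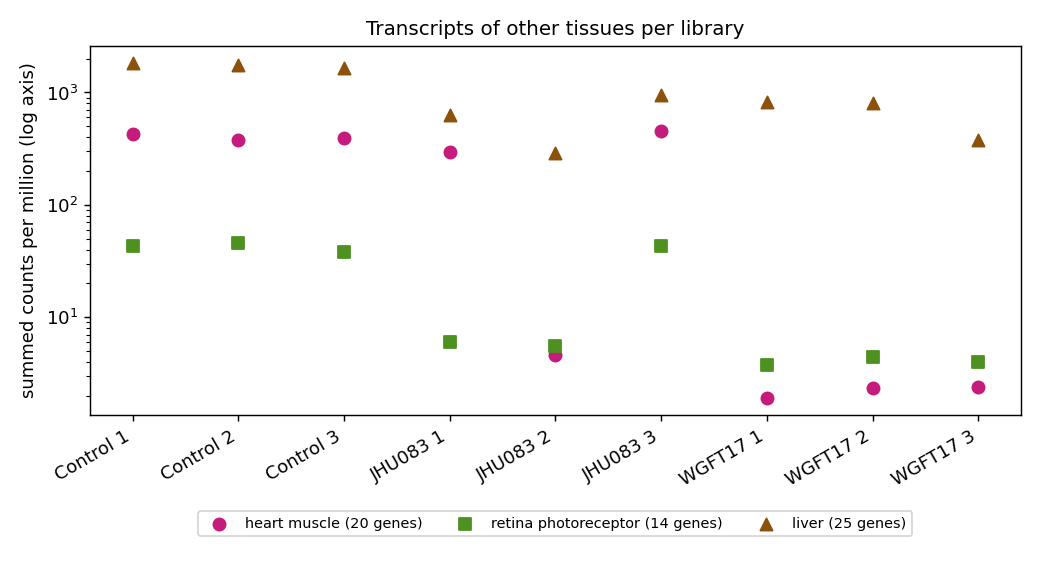
Summed CPM (log axis) of heart muscle, photoreceptor and liver genes in each of the 9 libraries, 1 point per list and library. Control replicates 1 to 3 and JHU083 replicate 3 lie at 38.1 to 46.2 for the photoreceptor genes and the other 5 libraries at 3.79 to 5.99.

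The split limits each comparison differently. For JHU083 against Control, libraries that carry retinal transcripts can be compared only through JHU083 replicate 3, and all 3 Control libraries stand on that side. WGFT17 can be compared with JHU083 on the other side through JHU083 replicates 1 and 2. No value within either side can be had for WGFT17 against Control, because each group lies wholly on its own side; there a fit with the split as a term rests on the JHU083 libraries and assumes that the split acts alike in all groups. Values with the split as a term are called split-adjusted below. In JHU083 against Control they rest on JHU083 replicate 3 alone. In WGFT17 against Control they rest on that library as well, the only carrying library of its group. In both comparisons with Control they are given as sizes. They were chosen after the data were seen.

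JHU083 against Control asks what an antagonist of glutamine does to the transcripts of macrophages. Cells need glutamine for nucleotides, for other amino acids and to feed the tricarboxylic acid cycle. When amino acids run short, uncharged tRNA activates a stress pathway that ends in the transcription factor ATF4, which turns on amino acid synthesis, transport and tRNA charging. Of the 11798 genes tested with edgeR's quasi-likelihood test, 2831 (24.0%) changed, 1351 higher and 1480 lower in JHU083 after Benjamini-Hochberg adjustment. Most changes were small, with a median absolute log2 change of 0.36; 32 genes were at least 2-fold higher and 139 at least 2-fold lower. Of all tested genes, 5155 (43.7%) showed no overlap between the 3 JHU083 and the 3 Control libraries, where chance gives 10%; among the changed genes this held for 2573. With the split as a term, JHU083 replicate 3 alone stands against Control, so the count of calls of that fit is not used as a result. The share of higher genes was 47.7% with TMM factors and 58.7% with library totals alone (1738 higher and 1222 lower), so it depended on the scaling. It was 71.6% in a limma fit of log2 FPKM (2524 higher and 1003 lower), where unit, scaling and test all differ. A count without 1 library also moved: 1534 genes were called without Control replicate 2, 1568 without Control replicate 3 and 3731 without JHU083 replicate 3.

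Of 44 gene lists tested with camera at a preset correlation of 0.01, 18 shifted in JHU083 against Control, 3 up and 15 down. None of the 18 held with a correlation estimated from the data, and the adjusted p then ranged from 0.149 to 0.572. The tests therefore rank lists against other genes and do not show that a whole list would shift in other libraries.

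The amino acid response list, made of ATF4 targets, was shifted down. Of its 34 tested genes, 4 were higher, 15 lower and 15 did not pass; adjusted over the list alone, 5 were higher and 18 lower. The median log2 change was -0.23 (split-adjusted -0.33), with a camera adjusted p = 0.000204 and adjusted p = 0.19 with an estimated correlation. The amino acid transporter gene Slc7a5 had 17.6 ± 1.27 FPKM (mean ± SD, n = 3) against 26.6 ± 2.01 in Control, a log2 change of -0.69 (adjusted p = 0.000514). Asns, which encodes the glutamine-using asparagine synthetase, fell by 0.41 on the log2 scale (adjusted p = 0.0018) and Chac1 by 0.60 (adjusted p = 0.00581). For Trib3 and Ddit3, classic ATF4 targets, no change was detected (adjusted p = 0.0877 and 0.0888). Of the 20 aminoacyl-tRNA synthetases, 12 were lower, 0 higher and 8 did not pass; adjusted over the list alone, 15 were lower. Their median was -0.19 (split-adjusted -0.21), with adjusted p = 4.54e-06 and adjusted p = 0.149 with an estimated correlation. Gars, the glycyl-tRNA synthetase gene, fell by 0.43 on the log2 scale (adjusted p = 0.00044).

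Genes of protein synthesis and respiration were lower by small amounts. Of 47 ribosomal protein genes, 37 were lower, 0 higher and 10 did not pass; adjusted over the list alone, 40 were lower. The median was -0.31 (split-adjusted -0.25), with adjusted p = 2.01e-17 and adjusted p = 0.19 with an estimated correlation. Rps16 had 96.6 ± 3.95 FPKM against 131 ± 6.45 (adjusted p = 0.000438). Ribosomal protein genes have many processed pseudogenes, so the placement of their reads is less certain. Of 46 nuclear genes of oxidative phosphorylation, 26 were lower, 0 higher and 20 did not pass; adjusted over the list alone, 33 were lower. The median was -0.27 (split-adjusted -0.27), with adjusted p = 8.38e-12 and adjusted p = 0.149 with an estimated correlation. Ndufa4 fell by 0.58 on the log2 scale (adjusted p = 0.0013) and Atp5o by 0.36 (adjusted p = 0.000785). Of 29 tricarboxylic acid cycle genes, 8 were lower, 0 higher and 21 did not pass, the same counts as when adjusted over the list alone. The median was -0.12 (split-adjusted -0.18), with adjusted p = 0.00234 and adjusted p = 0.198 with an estimated correlation. With a mean FPKM of at least 5 it was -0.0775 and not called (adjusted p = 0.0672). The ribosomal and oxidative phosphorylation lists hold short transcripts, and the log2 change of this comparison followed transcript length across genes (Spearman's rho = 0.384 over 11791 genes, which are not independent replicates).

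MYC targets and ribosome biogenesis genes, which promote growth, followed the same direction. Of 35 genes, 12 were lower, 0 higher and 23 did not pass; adjusted over the list alone, 19 were lower. Their median was -0.21 (split-adjusted -0.17), with adjusted p = 4.97e-06 and adjusted p = 0.149 with an estimated correlation. The spermidine synthase gene Srm fell by 0.66 on the log2 scale (adjusted p = 0.000488), and Myc itself by 0.32 (adjusted p = 0.00752). Of 24 cholesterol synthesis genes, 12 were lower, 0 higher and 12 did not pass; adjusted over the list alone, 14 were lower. Here the median was -0.31 (split-adjusted -0.34), with adjusted p = 8.21e-07 and adjusted p = 0.249 with an estimated correlation. Fdps, which encodes farnesyl diphosphate synthase (chromosome 3, 89093588 to 89101959), had 13.2 ± 0.868 FPKM against 20.4 ± 1.52, a log2 change of -0.71 (adjusted p = 0.000328). Of 17 fatty acid synthesis genes, 1 was higher, 7 lower and 9 did not pass; adjusted over the list alone, 1 was higher and 9 lower (median -0.23, split-adjusted -0.20, adjusted p = 0.00333, and adjusted p = 0.19 with an estimated correlation).

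Enzymes that use or make glutamine were not called by camera (adjusted p = 0.0678), but fry, which does not set a list against other genes, found them lower on balance (adjusted p = 0.00305). Of 22 genes, 1 was higher, 6 lower and 15 did not pass, with a median of -0.09, and 5 of 20 alternatives passed. Cad, which starts pyrimidine synthesis from glutamine, fell by 0.39 on the log2 scale (adjusted p = 0.00574). No change was detected for Glul, Ppat, Ctps or Gfpt1 (adjusted p = 0.246, 0.606, 0.635 and 0.672).

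DNA replication and interferon genes went the other way. Of 33 DNA replication (S phase) genes, 8 were higher, 0 lower and 25 did not pass; adjusted over the list alone, 10 were higher. The median was 0.13 (split-adjusted 0.07), with adjusted p = 0.00192 and adjusted p = 0.249 with an estimated correlation. Pcna, the sliding clamp of DNA polymerase, had 122 ± 6.48 FPKM against 91.8 ± 3.22 (adjusted p = 0.00291). The mitosis list had a median of 0.04 (6 higher, 2 lower and 28 not passing of 36, adjusted p = 0.404). Of 36 interferon-stimulated genes, 13 were higher, 0 lower and 23 did not pass; adjusted over the list alone, 14 were higher and 1 lower. Their median was 0.22 (split-adjusted 0.45), with adjusted p = 0.000457 and adjusted p = 0.392 with an estimated correlation; without JHU083 replicate 3 the adjusted p was 0.0824. Parp14 (chromosome 16, 35832874 to 35871544) had 10.5 ± 0.584 FPKM against 5.78 ± 0.556, which is 1.70-fold higher (log2 0.76, adjusted p = 0.000346), and Stat2 rose by 0.57 on the log2 scale (adjusted p = 0.000785).

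Several single genes of early immune activation were lower, though the 2 lists of such genes were not called. Of 24 NF-kB feedback and early response genes, 1 was higher, 5 lower and 18 did not pass (adjusted p = 0.404). Of 16 classical activation genes, 3 were higher and 3 lower (adjusted p = 0.737). Tnf had 7.23 ± 1.73 FPKM against 13.1 ± 0.992, a log2 change of -0.95 (split-adjusted -0.59, adjusted p = 0.00215). Ptgs2, which encodes cyclooxygenase-2, was 2.2-fold lower (adjusted p = 0.000119), Zfp36 fell by 0.99 on the log2 scale (adjusted p = 8e-06) and Egr1 by 0.91 (adjusted p = 3.32e-05). Nos2, Il1b and Il6 had mean FPKM of 1.00 or less in all 3 groups and were not tested. Cd274, which encodes the checkpoint ligand PD-L1 (chromosome 19, 29367455 to 29388095), was 1.36-fold higher (8.71 ± 0.502 against 6.00 ± 0.517 FPKM, adjusted p = 0.00247). For the macrophage markers Mrc1, Csf1r and Adgre1 no change was detected (adjusted p = 0.92, 0.745 and 0.286).

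Several of the largest falls among genes with at least 5 FPKM in Control were in genes of other cells. S100a9, a gene highly expressed in neutrophils but not in them alone (chromosome 3, 90692632 to 90695721), had 3.31 ± 0.399 FPKM against 17.2 ± 3.87 in Control. It was 5.51-fold lower (log2 -2.46, SE 0.25, split-adjusted -2.30, adjusted p = 0.000339). Of the 9 neutrophil genes, 5 were lower, 0 higher and 4 did not pass; adjusted over the list alone, 6 were lower. Their median was -1.02 (adjusted p = 0.00556, and adjusted p = 0.178 with an estimated correlation) and -0.70 split-adjusted. The call held in 16 of 20 alternatives. Of 17 stromal and endothelial genes, 10 were lower, 0 higher and 7 did not pass, with the same counts adjusted over the list alone. Their median was -0.41 (split-adjusted -0.57), with adjusted p = 4.97e-06 and adjusted p = 0.19 with an estimated correlation. Col1a1, a collagen gene, had 546 ± 50.3 FPKM against 866 ± 30.0 (log2 -0.76, adjusted p = 0.000149). Liver genes were among these falls too: Serpina1e, Pzp, Itih3 and Apcs were lower, and they follow the liver transcripts whose sums were lower in all 3 JHU083 libraries. With the split as a term, their log2 changes were -1.26, -0.95, -0.99 and -1.16, from JHU083 replicate 3 alone.

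The remaining called lists were smaller shifts. Of 15 chemokines 3 were lower, of 7 B cell genes 2, of 24 glycolysis genes 9 (2 higher), of 29 purine and pyrimidine synthesis genes 7 (1 higher) and of 23 unfolded protein response genes 8 (1 higher). Adjusted over the list alone, 3, 2, 11, 8 and 8 were lower and the higher genes numbered the same. Chemokines, B cell genes, glycolysis, purine and pyrimidine synthesis and the unfolded protein response had medians of -0.26, -0.20, -0.15, -0.08 and -0.11, with adjusted p = 0.0372, 0.039, 0.00989, 0.0167 and 0.0053; their adjusted p with an estimated correlation was 0.495, 0.249, 0.572, 0.178 and 0.309. Split-adjusted, the medians in the same order were -0.17, -0.38, -0.33, -0.17 and -0.12. These rest on JHU083 replicate 3 alone, so they neither keep nor end a call. The median of purine and pyrimidine synthesis was 0.0072 in the FPKM fit. At pseudocount 0.1, that of the unfolded protein response was -0.0197 and its call ended (adjusted p = 0.0611). Leaving out JHU083 replicate 3 gave adjusted p = 0.0824 for B cell genes and for glycolysis, and leaving out Control replicate 3 gave 0.118 for chemokines. The inflammasome list was higher (median 0.18, 7 higher and 1 lower of 16, or 8 and 1 adjusted over the list alone, adjusted p = 0.0131, and adjusted p = 0.178 with an estimated correlation), with adjusted p = 0.0699 without JHU083 replicate 3.

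WGFT17 against Control asks what the coded compound does to the same cells. Its changes were larger and more numerous. GM-CSF also drives macrophages and their precursors to divide, and cultures started from marrow can hold other adherent cells that make collagen, such as fibroblasts. Of the tested genes, 6837 (58.0%) changed, 3300 higher and 3537 lower, with a median absolute log2 change of 0.51. At least 2-fold changes were mostly falls: 252 genes were higher and 1269 lower by that much. No overlap was seen for 8636 genes (73.2%, chance 10%), and for 6493 of those changed. With the split as a term this comparison also rests on JHU083 replicate 3, so no count of calls is given for that fit. A term for heart transcripts, which all 3 Control libraries and JHU083 replicates 1 and 3 carry, links the sides only through JHU083 replicate 2. The share of higher genes was 48.3% with TMM, 60.9% in the FPKM fit (4490 higher and 2879 lower) and 61.5% after quantile normalization (4537 higher and 2836 lower). The median log2 change was 0.115 after quantile normalization and 0.00441 with TMM. Of the 44 lists, 20 shifted, 7 up and 13 down, and 0 of them held with an estimated correlation.

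The amino acid response was the list with the smallest p among those that rose. Of 34 genes, 24 were higher, 0 lower and 10 did not pass; adjusted over the list alone, 25 were higher. The median was 0.78 (split-adjusted 0.68), with adjusted p = 2.39e-09 and adjusted p = 0.0896 with an estimated correlation. Trib3 (chromosome 2, 152337422 to 152344032) had 62.1 ± 1.58 FPKM against 6.73 ± 1.05 and was 8.55-fold higher (log2 3.10, SE 0.12, adjusted p = 2.44e-09). Ddit3, which encodes the stress transcription factor CHOP, had 78.8 ± 2.11 FPKM against 9.88 ± 0.953 and was 7.39-fold higher (adjusted p = 1.42e-10). Slc7a11, the cystine transporter gene (chromosome 3, 49892526 to 50443614), was 7.87-fold higher (adjusted p = 2.6e-09), and Asns rose by 0.52 on the log2 scale (adjusted p = 3.27e-05). Of 20 aminoacyl-tRNA synthetases, 11 were higher, 2 lower and 7 did not pass; adjusted over the list alone, 12 were higher and 2 lower (median 0.18, split-adjusted 0.25, adjusted p = 0.0108, and adjusted p = 0.208 with an estimated correlation). After quantile normalization their adjusted p was 0.0691.

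NRF2 turns on genes against oxidants and electrophiles. Of 21 NRF2 targets, 17 were higher, 3 lower and 1 did not pass, the same as adjusted over the list alone. Their median was 0.70 (split-adjusted 0.59), with adjusted p = 1.69e-06 and adjusted p = 0.208 with an estimated correlation. Nqo1 had 29.1 ± 2.62 FPKM against 3.83 ± 0.537 and was 7.03-fold higher (adjusted p = 2.15e-08). Hmox1, the heme oxygenase gene, was 2.90-fold higher, from 367 ± 7.52 to 1150 ± 58.0 FPKM. Of 36 lysosome and autophagy genes, 25 were higher, 3 lower and 8 did not pass, with the same counts adjusted over the list alone. Their median was 0.44 (split-adjusted 0.33), with adjusted p = 1.24e-06 and adjusted p = 0.208 with an estimated correlation. The cargo receptor gene Sqstm1 was 4.07-fold higher (644 ± 27.6 against 146 ± 5.05 FPKM, adjusted p = 4.58e-09), and Npc1, which exports cholesterol from lysosomes, rose by 1.30 on the log2 scale.

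Immune genes moved in both directions. Of 36 interferon-stimulated genes, 26 were higher, 3 lower and 7 did not pass, with the same counts adjusted over the list alone. Their median was 0.77 (split-adjusted 0.99), with adjusted p = 8.55e-07 and adjusted p = 0.208 with an estimated correlation. Oas3, a sensor of double-stranded RNA, was 3.09-fold higher (7.91 against 2.37 FPKM). Cd274 was 4.25-fold higher (27.5 ± 1.18 against 6.00 ± 0.517 FPKM, log2 2.09, adjusted p = 1.68e-09). Cd86, a ligand that costimulates T cells, was 3.24-fold higher (14.8 ± 0.957 against 4.23 ± 0.326 FPKM, adjusted p = 1.2e-08). Mrc1, the mannose receptor gene often used as a marker of alternative activation, was 2.05-fold lower (60.7 ± 4.85 against 115 ± 11.1 FPKM, adjusted p = 5.75e-07). For Tnf and Adgre1 no change was detected (adjusted p = 0.291 and 0.454). Of 15 chemokines, 13 were lower, 0 higher and 2 did not pass, with the same counts adjusted over the list alone; the median was -1.20 (split-adjusted -0.91), with adjusted p = 5.21e-05 and adjusted p = 0.208 with an estimated correlation. Cxcl5, which attracts neutrophils, was 12.3-fold lower, and Cxcl16 fell by 1.26 on the log2 scale.

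Nearly all cell division genes were lower. All 36 mitosis genes were lower, over all genes and adjusted over the list alone, with a median of -2.91 (split-adjusted -2.68), adjusted p = 1.29e-22 and adjusted p = 0.0896 with an estimated correlation. Plk1, a kinase needed to enter and leave mitosis (chromosome 7, 122159439 to 122169873), had 1.57 ± 0.085 FPKM against 18.9 ± 0.875 and was 13-fold lower (log2 -3.70, SE 0.077, adjusted p = 8.24e-11). Of 33 S phase genes, 31 were lower, 0 higher and 2 did not pass, with the same counts adjusted over the list alone. Their median was -1.08 (split-adjusted -1.05), with adjusted p = 7.14e-12 and adjusted p = 0.0896 with an estimated correlation. Rrm2, a subunit of ribonucleotide reductase, was 5.72-fold lower.

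Stromal and endothelial genes fell as far. All 17 were lower, also adjusted over the list alone, with a median of -2.85 (split-adjusted -3.04), adjusted p = 7.23e-13 and adjusted p = 0.0896 with an estimated correlation. Col3a1 (chromosome 1, 45311538 to 45349706) had 2.21 ± 0.15 FPKM against 62.3 ± 7.62 and was 30.4-fold lower, and Col1a1 was 9.67-fold lower (96.5 ± 3.39 against 866 ± 30.0 FPKM, adjusted p = 8.24e-11). The matrix protease and wound-response list had 5 genes higher, 18 lower and 2 not passing of 25; adjusted over the list alone, 6 were higher and 18 lower (median -0.70, split-adjusted -0.89, adjusted p = 0.00115, and adjusted p = 0.208 with an estimated correlation). Thbs1, a secreted matrix glycoprotein gene, fell by 2.34 on the log2 scale. These falls stand beside those of heart transcripts: Actc1 and Mb had 27.0 ± 2.06 and 22.5 ± 1.11 FPKM in Control and were listed at 0 in all WGFT17 libraries. Neutrophil genes were lower as well (1 higher, 6 lower and 2 not passing of 9, median -1.77, adjusted p = 0.0227, and adjusted p = 0.208 with an estimated correlation). Their split-adjusted median was -0.65, and adjusted p ran from 5.83e-06 to 0.344 over 20 alternatives. The progenitor list of 5 genes had 4 lower (median -1.79, adjusted p = 0.0224, and adjusted p = 0.208 with an estimated correlation). Split-adjusted, the median was -1.77.

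Lipid synthesis was lower. Of 24 cholesterol synthesis genes, 23 were lower, 0 higher and 1 did not pass, with the same counts adjusted over the list alone; the median was -1.17 (split-adjusted -1.14), with adjusted p = 7.61e-11 and adjusted p = 0.208 with an estimated correlation. Fdps had 5.60 ± 0.297 FPKM and was 3.91-fold lower than in Control (adjusted p = 2.57e-09). Of 17 fatty acid synthesis genes, 1 was higher, 8 lower and 8 did not pass, with the same counts adjusted over the list alone (median -0.20, split-adjusted -0.41, adjusted p = 0.0138, and adjusted p = 0.208 with an estimated correlation). The desaturase gene Fads2 was 14.4-fold lower.

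Respiratory genes encoded in mitochondrial DNA were lower before the split was taken into account. Of 13, 1 was higher, 10 lower and 2 did not pass; adjusted over the list alone, 1 was higher and 11 lower. The median was -0.63 (adjusted p = 0.00499, and adjusted p = 0.481 with an estimated correlation), but split-adjusted it was -0.18, and adjusted p over 20 alternatives ran from 3.12e-05 to 0.835. Mitochondrial genes took 2.52% to 2.56% of the counts in Control, 2.19%, 2.1% and 2.96% in JHU083 replicates 1 to 3, and 1.56% to 1.73% in WGFT17. Nuclear genes of oxidative phosphorylation had a median of -0.29 (split-adjusted -0.27; 1 higher, 29 lower and 16 not passing of 46, or 2 higher and 29 lower adjusted over the list alone, adjusted p = 0.000215, and adjusted p = 0.208 with an estimated correlation), which was -0.14 and no longer called with GC and length trends removed (adjusted p = 0.108). Purine and pyrimidine synthesis was lower by a median of -0.19 (3 higher, 14 lower and 12 not passing of 29, or 3 higher and 15 lower adjusted over the list alone, adjusted p = 0.0185, and adjusted p = 0.188 with an estimated correlation). Camera called neither the enzymes that use or make glutamine (8 higher, 3 lower and 11 not passing of 22, adjusted p = 0.275) nor ribosomal proteins (4 higher, 23 lower and 20 not passing of 47, adjusted p = 0.0648). Fry found the first higher and the second lower on balance, each at adjusted p = 0.0344. MYC targets had 16 higher and 4 lower of 35, MHC class I genes 13 higher and 3 lower of 23 and B cell genes 4 lower of 7, with the same counts adjusted over the list alone. Their medians were 0.12, 0.295 and -0.28, and adjusted p = 0.208, 0.35 and 0.208 with an estimated correlation. Adjusted p was 0.0452, 0.0473 and 0.0452, and 14 of 20, 10 of 20 and 12 of 19 alternatives passed. Adjusted p for MYC targets was 0.0811 without Control replicate 1, 0.0565 without WGFT17 replicate 3, 0.109 after quantile normalization and 0.0619 with a term for heart transcripts. Split-adjusted, the medians were 0.177 for MHC class I genes and -0.641 for B cell genes.

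Largest of the rises with at least 5 FPKM were single genes of varied function. Avil, which encodes an actin-binding protein, was 73.4-fold higher (31.8 ± 2.49 against 0.40 ± 0.13 FPKM, log2 6.20, adjusted p = 7.53e-08). Ptgir, the prostacyclin receptor gene, was 10.6-fold higher (adjusted p = 8.51e-10) and the clotting factor gene F5 10.4-fold higher (adjusted p = 6.6e-10). Cebpb was among them with a log2 change of 4.02, but it follows the split of libraries: split-adjusted, its log2 change was -0.63, and adjusted p over 20 alternatives ran from 6.25e-12 to 0.101. Among the largest falls, Cnn1, a contractile gene of smooth muscle, was 46.9-fold lower (adjusted p = 9.83e-11), and Ngp, a neutrophil granule gene, was 77.3-fold lower.

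WGFT17 against JHU083 sets the drugs against each other without the Control libraries. All 3 WGFT17 libraries and JHU083 replicates 1 and 2 lack retinal transcripts, so the split-adjusted values here come from libraries on the same side of that split. They are not alike in heart transcripts, at 294 CPM in JHU083 replicate 1, 4.59 in replicate 2 and 1.9 to 2.39 in WGFT17. By these transcripts only JHU083 replicate 2 stands on the side of WGFT17. Of the tested genes, 5277 (44.7%) differed, 2403 higher and 2874 lower in WGFT17, with a median absolute log2 change of 0.471; 165 were higher and 942 lower by at least 2-fold. No overlap was seen for 6296 (53.4%, chance 10%), and for 5099 of the changed. With the split as a term, 2616 genes were higher and 3086 lower. Quantile normalization gave 59.8% higher (3498 against 2350), where TMM gave 45.5%. Of 18 lists that shifted, 10 were higher and 8 lower in WGFT17. Of these, 6 also passed with an estimated correlation: the ATF4, synthetase and MYC lists higher, and the mitosis, S phase and stromal lists lower. With both the split as a term and an estimated correlation, 0 lists passed in any comparison.

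The amino acid response separated the drugs. Of 34 ATF4 targets, 29 were higher, 0 lower and 5 did not pass; adjusted over the list alone, 30 were higher. The median was 0.84 (split-adjusted 0.80), with adjusted p = 1.52e-16 and adjusted p = 0.0342 with an estimated correlation. Trib3 had 5.89 ± 0.831 FPKM in JHU083 and was 10.4-fold higher in WGFT17 (split-adjusted log2 3.34, adjusted p = 2e-09), and Asns was higher by 0.93 on the log2 scale. Of 20 synthetases, 15 were higher, 1 lower and 4 did not pass; adjusted over the list alone, 17 were higher and 1 lower. Their median was 0.39 (split-adjusted 0.40), with adjusted p = 1.86e-07 and adjusted p = 0.0354 with an estimated correlation. Of 35 MYC targets and ribosome biogenesis genes, 24 were higher, 1 lower and 10 did not pass, with the same counts adjusted over the list alone; the median was 0.365 (split-adjusted 0.33), with adjusted p = 1.86e-07 and adjusted p = 0.0342 with an estimated correlation. Myc itself was higher by 0.39 (adjusted p = 0.000613). Ribosomal proteins were higher in WGFT17 by a median of 0.18 (23 higher, 0 lower and 24 not passing of 47, split-adjusted 0.21, adjusted p = 8.56e-05, and adjusted p = 0.462 with an estimated correlation).

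Stress and immune lists were higher too. NRF2 targets had 18 genes higher, 1 lower and 2 not passing (median 0.77, split-adjusted 0.74, adjusted p = 3.57e-10, and adjusted p = 0.152 with an estimated correlation). Lysosome genes had 26 higher, 3 lower and 7 not passing (median 0.40, split-adjusted 0.38, adjusted p = 1.07e-08, and adjusted p = 0.176 with an estimated correlation). Interferon-stimulated genes had 25 higher, 3 lower and 8 not passing (median 0.41, split-adjusted 0.55, adjusted p = 1.64e-05, and adjusted p = 0.359 with an estimated correlation). Adjusted over the list alone, the 3 lists had 18, 28 and 26 genes higher and 2, 4 and 3 lower. Cd274 was 3.13-fold higher (adjusted p = 1.11e-08), Cd86 2.62-fold higher and Ptgs2 3.82-fold higher in WGFT17, whereas Mrc1 was 2.03-fold lower. The immune-suppressive ligand list was higher by a median of 0.34 (adjusted p = 0.0307, and adjusted p = 0.386 with an estimated correlation). Its adjusted p was 0.0528 without JHU083 replicate 3, 0.0526 split-adjusted and 0.069 after quantile normalization. With a mean FPKM of at least 5 its median was only 0.0656 (adjusted p = 0.119). Pentose phosphate and glutamine enzyme lists were higher by medians of 0.32 and 0.16 (adjusted p = 0.0236 and 0.0307, adjusted p = 0.386 and 0.176 with an estimated correlation, and 0.0818 for each with a term for heart transcripts). The immune-suppressive, pentose phosphate and glutamine enzyme lists had 8, 6 and 9 genes higher and 2, 0 and 3 lower, of 17, 8 and 22; adjusted over the list alone, 8, 6 and 11 were higher and 3, 0 and 3 lower.

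Division and stromal genes were lower in WGFT17 than in JHU083. Of 36 mitosis genes, 35 were lower, 0 higher and 1 did not pass (median -3.11, split-adjusted -3.10, adjusted p = 5.04e-28, and adjusted p = 0.0354 with an estimated correlation). Of 33 S phase genes, 32 were lower and 1 did not pass (median -1.20, split-adjusted -1.19, adjusted p = 2.55e-17, and adjusted p = 0.0342 with an estimated correlation). All 17 stromal genes were lower (median -2.34, split-adjusted -2.40, adjusted p = 4.11e-15, and adjusted p = 0.0354 with an estimated correlation). These counts were the same adjusted over the list alone. Plk1 was 11-fold and Col3a1 15.4-fold lower. Cholesterol synthesis had 22 genes lower, 0 higher and 2 not passing (median -0.84, split-adjusted -0.85, adjusted p = 1.79e-10, and adjusted p = 0.176 with an estimated correlation), and chemokines 11 lower, 0 higher and 4 not passing (median -0.74, split-adjusted -0.59, adjusted p = 0.000458, and adjusted p = 0.314 with an estimated correlation). Adjusted over the list alone, 23 cholesterol synthesis genes were lower, and 12 chemokines were lower and 1 higher. Matrix, progenitor and mitochondrially encoded lists were lower by medians of -0.56, -1.61 and -0.64 (adjusted p = 0.000319, 0.00688 and 0.0106, and adjusted p = 0.176, 0.165 and 0.595 with an estimated correlation), with 17 of 25, 4 of 5 and 9 of 13 genes lower and 17, 4 and 10 lower adjusted over the list alone. Split-adjusted, the medians were -0.605, -1.65 and -0.415, all still called; with a term for heart transcripts the mitochondrially encoded list had -0.363 and was not called (adjusted p = 0.122).

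**Figure D2:**
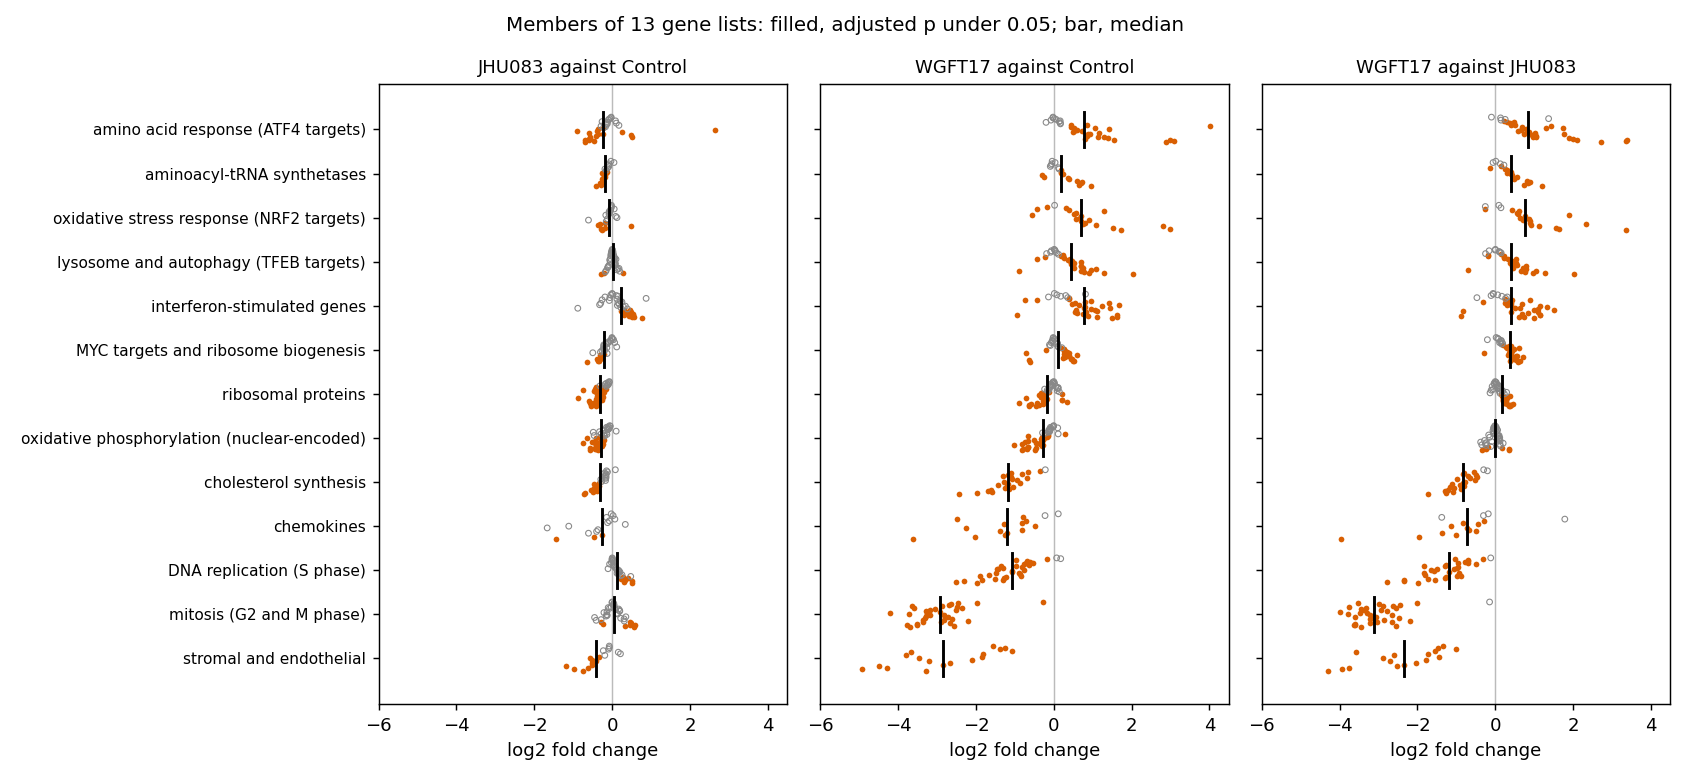
Log2 fold changes of the members of 13 gene lists in the 3 comparisons, 1 point per gene, filled where the adjusted p was under 0.05, with a bar at each list's median. The median of the ATF4 targets lies at -0.23, 0.78 and 0.84 from left to right, and that of the mitosis genes at 0.04, -2.91 and -3.11.

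The drugs can be compared by the genes that each changed against Control. Both share the 3 Control libraries, so chance in those libraries moves both results together. Of the 2831 genes changed by JHU083, 2074 (73.3%) changed in the same direction with WGFT17, 984 higher and 1090 lower; independent lists of these sizes would share 378 and 444. In 20 simulations with no group effect and no library split, at most 1 gene was shared. Few genes are called without an effect, so this does not bound the excess. Part of the excess over 378 and 444 may still come from the shared Control libraries, which at 3 are too few to be divided between the drugs. The library split may add to it as well. All Control libraries carry retinal transcripts, whereas all WGFT17 libraries and JHU083 replicates 1 and 2 do not. Genes that follow the split would thus change alike in both comparisons. So would genes that change with culture time, if Control cells were not kept for the same 36 h. Across the 11798 genes, which are not independent replicates, the log2 changes had a Pearson's r of 0.496, against a mean of 0.499 (0.406 to 0.611) in the simulations; their covariance was 0.163, against a mean of 0.0198 and a highest value of 0.027. Another 191 genes changed in opposite directions, 115 of them higher with JHU083 and lower with WGFT17 and 76 the reverse. All 191 also differed in the direct comparison. Slc7a11 was among them, with log2 changes of -0.38 and 2.98, as were F5 (-0.41 and 3.38), Rrm2 (0.27 and -2.52) and Clspn (0.50 and -1.85).

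**Figure D3:**
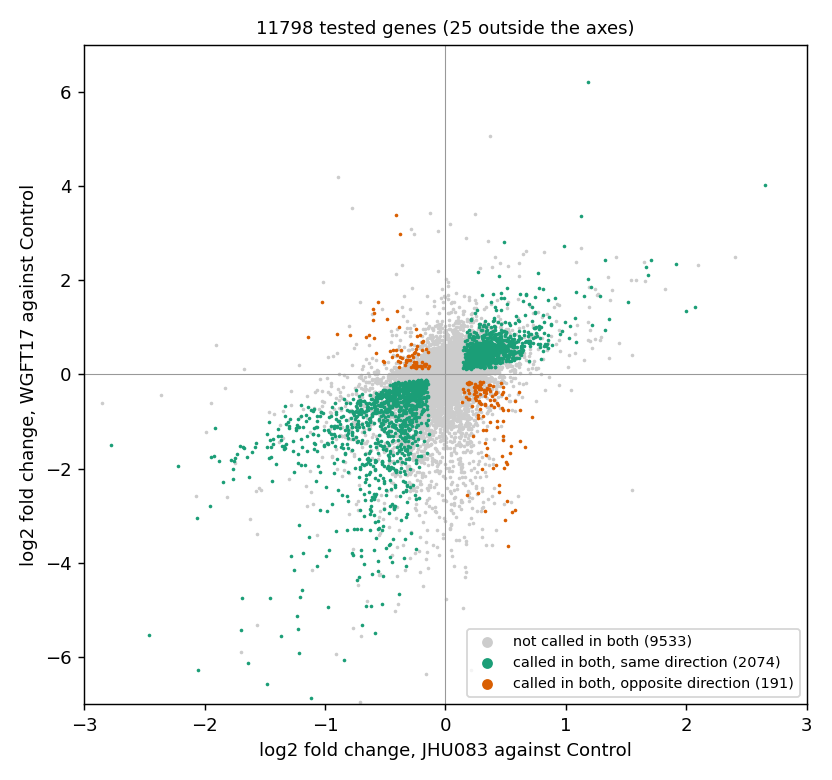
Log2 fold change against Control of each of the 11798 tested genes, with JHU083 on the horizontal and WGFT17 on the vertical axis, coloured by whether both comparisons called the gene in the same direction (2074) or in opposite directions (191). The vertical axis is wider than the horizontal one, and 25 genes lie outside the axes.

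**Figure D4:**
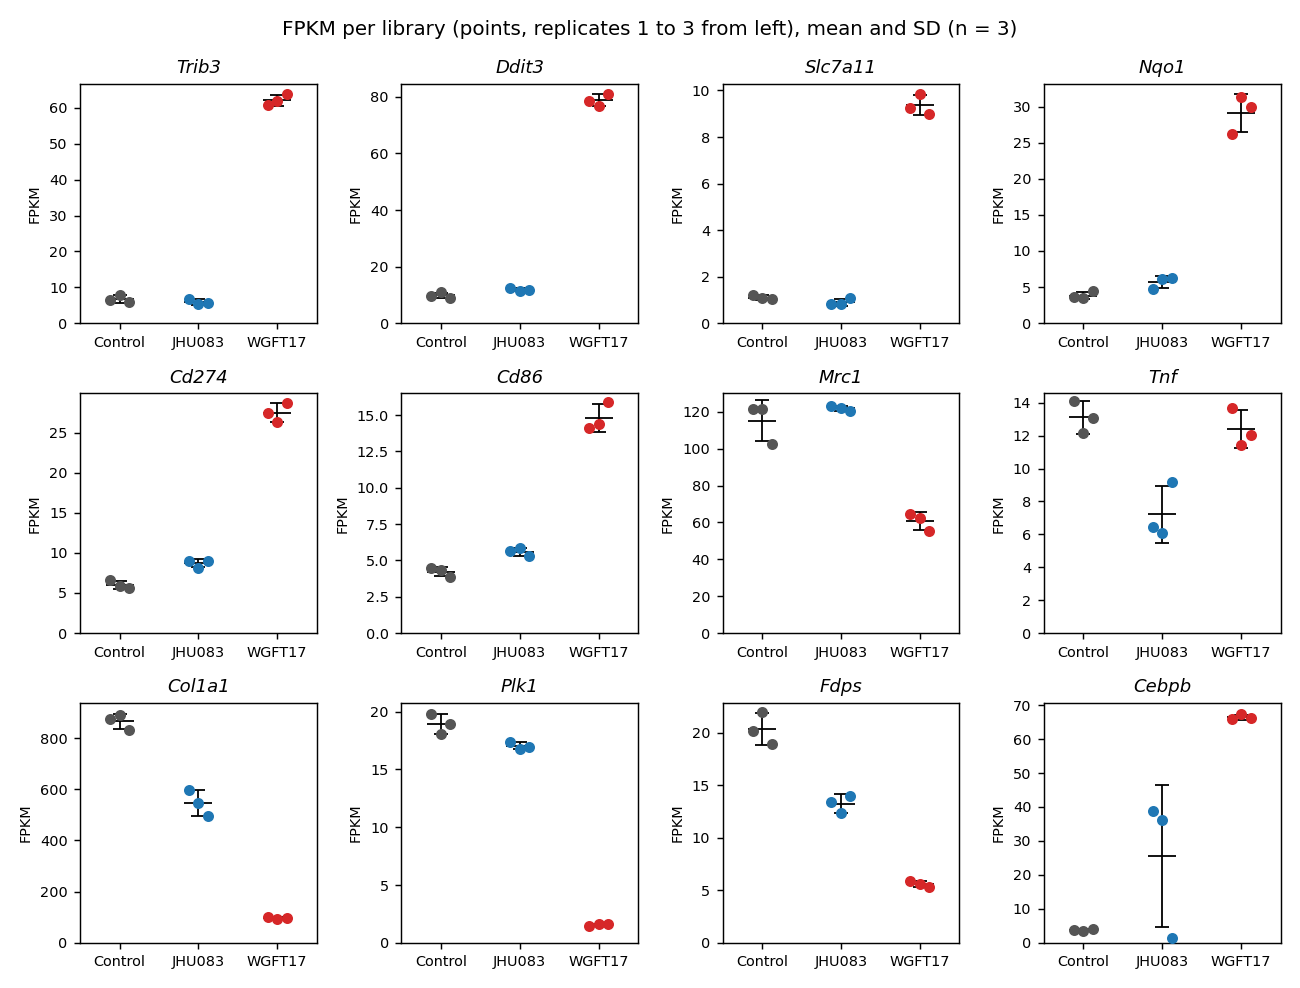
FPKM of 12 genes in each library (points, replicates 1 to 3 from left to right) with mean and SD (n = 3) for Control, JHU083 and WGFT17. Trib3, Ddit3, Slc7a11, Nqo1, Cd274 and Cd86 are highest in WGFT17, Col1a1, Plk1, Fdps and Mrc1 are lowest there, and Cebpb lies at 1.47 in JHU083 replicate 3 beside 38.8 and 36.3 in the other JHU083 libraries.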

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

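The tests of stromal cell share, of GC content and length on the mitosis list and of the library split were chosen after the result was seen; the divisions of the libraries were planned.

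Of the differences called in the direct comparison of WGFT17 with JHU083, 4 gene lists and 191 single genes had also been called in opposite directions against Control. ATF4 targets had a median of -0.23 with JHU083 and 0.78 with WGFT17, and of 0.838 between the drugs. For the aminoacyl-tRNA synthetases the medians were -0.19 and 0.18, and 0.393 between the drugs; the second lost its call after quantile normalization (adjusted p = 0.0691). MYC targets had -0.21 and 0.12, and 0.365 between the drugs; the call of the middle value ended without Control replicate 1 (0.144, adjusted p = 0.0811) and without WGFT17 replicate 3 (0.132, adjusted p = 0.0565), after quantile normalization (0.179, adjusted p = 0.109) and with a term for heart transcripts (0.139, adjusted p = 0.0619), though the median did not shrink. S phase genes had 0.13 and -1.08, and -1.20 between the drugs. With an estimated correlation none of these 8 calls against Control held (adjusted p = 0.0896 to 0.249), and the 4 calls between the drugs held (0.0342 to 0.0354) but ended once the split was a term as well. Of the 191 genes, 115 were higher with JHU083.

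The 6 libraries of a comparison can be divided into 3 and 3 in 10 ways, which is too few for a share under 0.05. In fits of 2 groups, the real division gave 1976 changed genes for JHU083 against Control, 7601 for WGFT17 against Control and 4785 between the drugs, and 1 of 10 divisions, the real one, reached that count in each. The highest other counts were 1, 0 and 0. For gene lists the real division gave 18, 21 and 18 calls and the highest other 18, 18 and 17, so that 2, 1 and 1 of 10 reached it. The other divisions gave 5 to 18, 9 to 18 and 7 to 17 list calls, so that camera at the preset correlation calls many lists in divisions that mix the groups; the 18 for JHU083 came from Control replicates 1 and 3 with JHU083 replicate 2.

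The fall of the mitosis list with WGFT17 was weighed against GC and length trends and against the library split. That of the stromal and cell cycle lists was weighed against a smaller share of stromal cells. With GC and length trends removed, the mitosis median in WGFT17 against Control was -3.07. Against JHU083 replicates 1 and 2 alone, on the same side of the library split, it was -3.10. For the mitosis list, both values argue against the trends and the split as the whole cause. The second does so for the fall from JHU083, not from Control. Fewer stromal cells of 1 kind would lower every stromal gene alike only if no other cells of the culture express these genes. The 17 members ranged over 3.85 on the log2 scale, from -1.07 for Pdgfra to -4.93 for Col3a1, where 4 times the highest SE was 0.98. Expression in other cells was not measured, so this range does not decide whether the share of stromal cells fell. Fewer dividing stromal cells and slower division of macrophages cannot be told apart for the cell cycle lists: with JHU083 the mitosis median was 0.0441 while stromal genes fell, but that is another drug and bounds nothing for WGFT17. An effect of WGFT17 on division, and a loss of stromal cells of 1 or more kinds, may both contribute and were not separated.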

How the results depend on the processing

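The tests with the FPKM fit at pseudocount 1, DESeq2, divided counts, filterByExpr, library totals, terms for retinal or heart transcripts, GC and length trends and genes of other tissues left out were chosen after the result was seen. Of the counts of genes, lists or shared calls under an alternative, 154 stayed within 1.5 times the reported count and 20 did not. With a minimum fold of 2, the gene counts were 171, 1521 and 1107 for JHU083 and WGFT17 against Control and WGFT17 against JHU083, and 126 calls were shared, because fewer genes can pass. With a mean FPKM of at least 5, WGFT17 against Control gave 4151 and WGFT17 against JHU083 3305, because fewer genes were tested. A term for heart transcripts gave 3525 for WGFT17 against Control and 1054 shared calls. Only JHU083 replicate 2 then links the sides, but whether this lowered the counts was not tested. An estimated correlation left 0, 0 and 6 lists, and with the retinal term 0, 0 and 0; fry gave 39 for WGFT17 against Control and 35 between the drugs, and it asks another question. Leaving out each library in turn gave 1534 to 3731 genes for JHU083 against Control (1534 and 1568 without Control replicates 2 and 3, 3731 without JHU083 replicate 3), 6007 to 7598 for WGFT17 against Control, 4471 to 5713 between the drugs, and 1154 to 2703 shared calls (1154 and 1176 without Control replicates 2 and 3). The cause was not tested.

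Among named genes, 8224 values under alternatives kept direction and side of the threshold, 150 lost their call and 32 gained one. Direction changed in 29 values of genes not called in the main test, and 5 values of called genes reversed. The reversed log2 values were 0.029 for Rplp1 in JHU083 against Control with GC and length trends removed, -0.63 for Cebpb and 0.48 for Slfn4 in WGFT17 against Control with the retinal term, and 2.27 for Myh6 and 3.40 for Myl3 with the heart term. Myh6 and Myl3 follow the heart transcripts, and Cebpb and Slfn4 follow the split of libraries. Slfn4 had 7.99 to 9.56 FPKM in Control, 8.48 in JHU083 replicate 3 and 0.09 to 0.23 in the other libraries. For Rplp1 the cause was not tested. Among list values, 2287 kept direction and side of the threshold, 165 lost their call and 88 gained one. Another 88, of lists not called in the main test, changed direction. With the replicate number as a block, the gene counts were 2330, 6530 and 4907, 1729 calls were shared and 17, 21 and 18 lists were called. Of 9 pairs of libraries with the same number, 1 had a residual correlation over 0.1, at 0.161. Of the 9 libraries, 4 matched their own number best. Pairing by number was thus not seen, but so few libraries cannot exclude it. Of simulated 1.5-fold changes, 66% to 68% were found, and smaller ones were missed more often. The simulations changed 200 genes, far fewer than were called in the data, so these shares are not the sensitivity there.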

Other observations

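The tests of foreign RNA, of a mislabelled library and of the library split were chosen after the result was seen; those of GC content and of matched lists were set before their results were seen. Most genes in the first paragraphs below were named by the fixed rule, and the WGFT17 values of Neat1, Malat1 and Xist, and H2-Aa and Cd74, were chosen after their values were seen.

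Neat1, Malat1 and Xist, RNAs that stay in the nucleus, were higher with both drugs; no list of such RNAs was tested. Neat1, the scaffold of paraspeckles (chromosome 19, 5824708 to 5845478), had 7.86 ± 1.41 FPKM in Control, 21 ± 1.39 in JHU083 (2.51-fold, adjusted p = 0.000339) and 46.0 ± 7.71 in WGFT17 (5.42-fold, adjusted p = 6.3e-08). Malat1, a nuclear speckle RNA, had 9.06 ± 2.11, 22 ± 2.49 (2.27-fold, adjusted p = 0.00121) and 39.8 ± 6.39 FPKM (4.07-fold, adjusted p = 1.24e-06). Xist, which coats the inactive X chromosome, was 1.84-fold and 2.07-fold higher. In JHU083 against Control, all 3 passed in each of 20 alternatives, with adjusted p of at most 0.00353, 0.00822 and 0.0178.

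With WGFT17, several single genes of antigen presentation and cell recruitment changed. H2-Eb1, a class II molecule that presents peptides to helper T cells, had 1.82 ± 0.366 FPKM against 11.8 ± 1.93 in Control (log2 -2.80, adjusted p = 1.84e-07). H2-Aa fell by 2.62 on the log2 scale and the invariant chain gene Cd74 by 1.46, whereas H2-D1, a class I molecule, was 2.22-fold higher (1170 ± 21.3 against 490 ± 17.4 FPKM). As a list, class II genes were not called by camera (2 higher, 8 lower and 2 not passing of 12, adjusted p = 0.0778), while fry found them lower on balance (adjusted p = 0.000531). The fractalkine receptor gene Cx3cr1 had 4.65 ± 0.467 FPKM against 20.6 ± 2.32 (log2 -2.25, adjusted p = 5.14e-09), and Itgax, the CD11c gene of dendritic cells and macrophages, fell by 2.34 on the log2 scale (adjusted p = 2.93e-08). Of 28 monocyte and macrophage identity genes, 9 were higher, 15 lower and 4 did not pass (adjusted p = 0.144, and 0.000168 with fry).

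The genes that set JHU083 replicate 3 apart from JHU083 replicates 1 and 2 were weighed as well. RNA of other tissues adds transcripts and barely dilutes the rest. The 58 genes at least 2-fold lower in replicate 3 thus argue against such RNA for those genes. A mislabelled Control library was tested by the genes that differ between JHU083 replicate 3 and Control, 3140 in number. This count does not decide the question, because a single library has no spread of its own and borrows that of the other libraries. In size, the median absolute log2 difference of JHU083 replicate 3 from each Control library was 0.182 to 0.226. Between Control libraries it was 0.0898 to 0.102. JHU083 replicate 3 thus lay further from the Control libraries than these from each other, but the cause was not shown. Removing each library's GC trend left 22.4% of the 1536 genes called (344), so a GC-linked difference between libraries is consistent with most of the small shifts. Of the 134 genes at least 2-fold apart, 53.7% (72) stayed so, among them Cebpb at -4.65 before and -4.12 after, which argues against GC content as their whole cause. Still open are a mislabelled library, separate handling of the libraries and a difference in culture, and no biological explanation was tested.

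The fall of ribosomal protein and oxidative phosphorylation genes with JHU083 was weighed against transcript properties. Of 10000 lists matched on length, GC content and level, 0.01% had a median as low as the ribosomal list. For the oxidative phosphorylation list it was also 0.01% (1 list each). Both lists thus fell further than single genes of like properties drawn together. The draws ignore that members of a list move together, and length was that of the longest annotated transcript. They therefore do not decide whether these properties are the whole cause. The matched lists were lower too, at -0.147 and -0.148 beside -0.313 and -0.274, so such trends may account for part of the fall. With the library split as a term, the ribosomal median was -0.25, but this rests on JHU083 replicate 3 alone and leaves the split open. Reads shared with pseudogenes were not tested, and an effect of the glutamine antagonist on genes of growth stays a hypothesis.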
